A study of Homo sapiens with 6 samples.

How the data were processed

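RNA sequencing libraries of ARPE-19 cells were analysed. ARPE-19 is an established human line of retinal pigment epithelium (RPE), the cell layer that supports the photoreceptors. Sodium iodate (NaIO3) is an oxidant that is toxic to this epithelium and is used to model its degeneration. Per the labels, cells were given NaIO3 for 24 h, and cells of 1 group were pretreated for 1 h with an agent that the labels call CaPB and do not spell out. The 2 groups, NaIO3 and NaIO3-CaPB, held 3 libraries each, 6 in all. Libraries without NaIO3, or with CaPB alone, were not analysed here, so every value below compares NaIO3 with CaPB against NaIO3 without it. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

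The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for single transcripts, per the file headers. The submitters' processing notes name cutadapt, HISAT2 2.0.5 and StringTie and the human build hg19, with no order, and the versions of cutadapt and StringTie are not given in the sources used here. Per the labels' protocols, total RNA was fragmented, primed at random and made into libraries with dUTP in the second strand, a chemistry that keeps the strand. Whether read assignment used the strand is not given in the sources used here, so values of genes that overlap an antisense gene are uncertain. FPKM values are already divided by depth and by transcript length, and they follow from how the software shared reads between isoforms. They hold no counts, so the depth of each library is unknown and neither a count model nor a counting interval was used. FPKM is relative: a rise in abundant transcripts lowers the values of all others in that library. Near-identical genes share reads, so values of single members of the AKR1C, metallothionein and HSPA1 families are uncertain.

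The table held 35101 transcripts by Ensembl identifier. Of these, 34973 matched a transcript of GENCODE release 29, which gave the gene, and the 128 without a match (0.118% of the summed FPKM) entered no gene. That release is on GRCh38 and the values on hg19, so it was used for names and transcript lengths and no coordinates are given. Transcripts of a gene were summed, which gave 11909 genes with a median of 2 listed transcripts. For 3571 genes there was 1 listed transcript. Of the matched transcripts, 99.8% are annotated as protein coding. The table consists of 3 sorted blocks: 31620 transcripts whose higher group mean was at least 0.500 FPKM, then blocks of 1997 and 1484 transcripts whose higher group mean did not exceed that level. What selection the blocks reflect is not given in the sources used here. A gene sum covers the listed transcripts, not necessarily all transcripts of the gene. Altogether 258 transcripts were at 0 in all 6 libraries. All 6 value columns were used. The 3 NaIO3-CaPB columns carry replicate numbers, and the 3 NaIO3 columns carry none. The latter are called NaIO3 library A, B and C here, which are names only.

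Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 10883 in number. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend and moderated variances. P-values were adjusted by Benjamini and Hochberg's method, and a gene was called at an adjusted p below 0.05. The effect is NaIO3-CaPB minus NaIO3, so rose and fell mean higher and lower in the NaIO3-CaPB libraries. A log2 fold change (log2FC) is on the log2(FPKM + 1) scale and understates the change of low genes. It is given with its standard error (SE), and FPKM are given as mean ± SD with n = 3 libraries per group. The same test was run on 21736 transcripts. Lists of genes were tested with camera in limma, 2-sided, with a preset correlation of 0.01 between genes, adjusted over the 27 of 31 lists that had at least 5 genes past the filter. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Camera does not use the intensity trend. Python 3.11.15 with pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the plots.

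The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took 3 kinds of genes. The first were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap. The next were, from each list, up to 4 called members with the smallest adjusted p, or the 1 with the smallest p where none passed. The last were a set reported whatever its result: HMOX1, NQO1, GCLM, SLC7A11, TXNRD1, SOD2, CAT, DDIT3, ATF3, CDKN1A, IL6, CXCL8, RPE65 and RLBP1. Genes named outside this rule are said to be so, and 1 gene that the rule takes is not reported here. The steps were tested on simulated data made from the 10883 genes with 200 changed genes. The test recovered 62% of genes changed by 1 log2 unit and 91% of those changed by 2, and 8 of 161 calls (4.97%) were unchanged genes. In a simulation over 21736 transcripts, 12% and 41% were recovered, so the transcript test had less power. With no list shifted, 0 lists were called in the simulation. A shift of -0.5 given to the NRF2 targets was called, with 0 other lists. Genes were drawn independently there, so the simulation could not show false list calls that arise when genes of a list are correlated. Each gene also had the same SD in both groups there. In the data the median SD of genes was 0.18 log2 units among NaIO3 and 0.11 among NaIO3-CaPB libraries. The share of calls that were unchanged genes may therefore differ in the data.

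The alternatives were another pseudocount, other filters, median-ratio scaling, quantile normalization, library weights, no intensity trend, and the omission of each library in turn. After the data were seen, 3 kinds of alternatives were added: the use of each gene's most abundant listed transcript, the omission of NaIO3 library B from counts of list members, and the gene alternatives applied to transcripts. Library B was chosen for this because it lay farthest from the NaIO3-CaPB libraries. Count-based tests were not used here, since the table holds FPKM.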

Results

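The libraries address how the transcripts of NaIO3-exposed ARPE-19 cells differ with CaPB pretreatment. Each of the 6 libraries had between 10720 and 10872 genes at 1 FPKM or more, and summed FPKM ran from 302825 to 309922. Transcripts encoded by mitochondrial DNA made up 9.175% to 9.917% of the summed FPKM, and the ranges of the groups overlapped. Libraries of the NaIO3-CaPB group resembled each other more than those of the NaIO3 group: Pearson's r of log2 values across genes was 0.9724 to 0.9749 within the former, 0.9566 to 0.9706 within the latter and 0.9306 to 0.9566 between groups. Genes are not independent replicates, so these values describe the libraries only. The first principal component held 47.3% of the variance and separated the groups. NaIO3-CaPB libraries lay between -22.59 and -20.69 on it, and NaIO3 libraries A, C and B at 10.95, 20.18 and 33.49.

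CaPB pretreatment went with lower transcripts of the oxidative stress genes HMOX1, NQO1 and GCLM and of the collagenase MMP1, and with higher transcripts of the hormone precursor NPPB, the ankyrin repeat protein ANKRD1, the actin-binding protein TAGLN and the sterol synthesis enzyme HMGCS1. NPPB, which encodes brain natriuretic peptide, rose from 2.02 ± 1.06 to 40.3 ± 0.624 FPKM (SD, n = 3 per group), with a log2FC of 3.85 (SE 0.28, limma adjusted p = 0.0029). ANKRD1 rose from 30.1 ± 7.15 to 265 ± 7.01 FPKM, or by 3.12 log2 units (SE 0.16, limma adjusted p = 0.00133). Among the 10 largest rises were JPH2, a junctophilin, with a log2FC of 2.83, HMGCS1 with 2.72, the membrane-bound metalloproteinase MMP24 with 2.47 and TAGLN with 2.46. The rest were C4BPB, a chain of the complement inhibitor C4b-binding protein (2.16), the matricellular protein CCN1 (2.13), the integrin ITGB4 (2.08) and the phospholipase PLCB4 (2.08). At the other end, MMP1 fell from 20.5 ± 16.6 to 0.282 ± 0.113 FPKM, with a log2FC of -3.61 (SE 0.74, limma adjusted p = 0.0325). The decoy receptor IL13RA2 had a log2FC of -2.91, the microtubule-associated NAV3 -2.52, the stress-induced OSGIN1 -2.46 and the aldo-keto reductase AKR1C3 -2.02. The remaining falls among the 10 largest were those of HMOX1 and GCLM, described with the NRF2 targets, and of the calcium-binding protein CALB2 (-1.87), the transcriptional regulator ID1 (-1.86) and the eye development gene MAB21L1 (-1.85). The calls of HMGCS1, MMP1, IL13RA2 and AKR1C3 were lost when some single libraries were left out. Each was lost without NaIO3-CaPB 3, at limma adjusted p of 0.0839, 0.11, 0.0612 and 0.0571, with the same direction. HMGCS1 and IL13RA2 also lost their calls without NaIO3-CaPB 1 or 2 or NaIO3 library C. MMP1 lost its call without any library but NaIO3 library A, and AKR1C3 also without NaIO3-CaPB 1. In many cases below too, a call said to be lost without 1 library was lost without others as well. Over all genes, omission of NaIO3-CaPB 1, 2 or 3 left 215, 245 and 169 calls against 1185 with all libraries. Such a loss was therefore general and does not single out that library or these genes. The NaIO3 mean of MMP1 was 12.4 FPKM without NaIO3 library B, and that of HMGCS1 was 9.2 FPKM without NaIO3 library A. With each gene's most abundant transcript alone, ITGB4 (log2FC 1.79, limma adjusted p = 0.0526), NAV3 (-2.27, 0.228), OSGIN1 (-1.73, 0.108) and CALB2 (lower by 1.00 log2 units, 0.0887) did not pass. MMP1 did not pass in that fit either (0.065), with an unchanged log2FC, since it has 1 listed transcript.

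Over all 10883 genes tested, limma called 1185 (10.9%), of which 581 rose and 604 fell, and 224 changed by at least 2-fold, with 140 higher and 84 lower. The groups did not overlap at 4279 genes (39.3%), where chance gives 10%, and 3313 genes had an unadjusted p under 0.05. The median log2FC of all tested genes was -0.02. Omitting 1 library left between 169 calls (without NaIO3-CaPB 3) and 1381 (without NaIO3 library A). With the most abundant transcript of each gene there were 469 calls, 413 of them shared with the 1185.

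**Figure D1:**
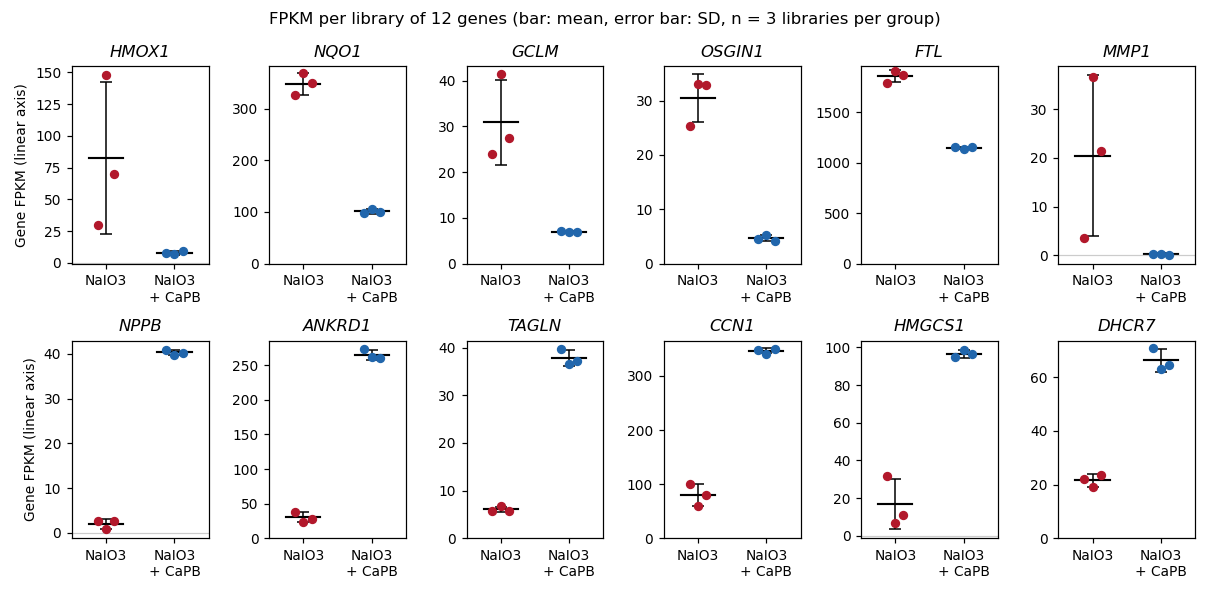
FPKM of 12 genes on linear axes, 1 point per library, for the NaIO3 and NaIO3-CaPB groups, with the mean as a horizontal bar and the SD as an error bar (n = 3). HMOX1, NQO1, GCLM, OSGIN1, FTL and MMP1 lay lower in all 3 NaIO3-CaPB libraries, and NPPB, ANKRD1, TAGLN, CCN1, HMGCS1 and DHCR7 lay higher; HMOX1 ranged from 29.8 to 148 FPKM among the NaIO3 libraries.

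Targets of NRF2, the transcription factor that induces antioxidant and detoxifying enzymes, fell together. Of 27 measured members, 14 fell, 0 rose and 13 did not pass, and adjusted over the list alone 19 fell and 1 rose. The median log2FC was -0.65 (camera adjusted p = 2.4e-09), with an adjusted p = 0.282 with an estimated correlation. NQO1, a quinone reductase, fell from 348 ± 21.3 to 101 ± 4.16 FPKM, 3.44-fold lower (log2FC -1.77, SE 0.07, limma adjusted p = 0.000761). HMOX1, the inducible haem oxygenase, averaged 82.7 ± 60.1 FPKM with NaIO3 and 7.77 ± 1.28 with CaPB added, 10.6-fold lower, or 6.43-fold without NaIO3 library B (log2FC -2.98, SE 0.53, limma adjusted p = 0.0241). GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, was 4.44-fold lower, at 6.96 ± 0.216 against 30.9 ± 9.32 FPKM. OSGIN1 was 6.47-fold lower, the ferritin light chain FTL 1.62-fold lower (1150 ± 10.7 against 1861 ± 61.4 FPKM), and TALDO1, of the pentose phosphate pathway, 1.55-fold lower. The cystine carrier SLC7A11 had a log2FC of -1.46 (limma adjusted p = 0.0276), and the thioredoxin reductase TXNRD1, at -0.52, missed the threshold (limma adjusted p = 0.058), except without NaIO3 library A (-0.66, 0.0182) and with library weights (-0.57, 0.00607). Its direction turned on its most abundant transcript of 14 (0.97, 0.688). The count of members that fell was 14 without NaIO3 library B also. The calls of HMOX1 and SLC7A11 were lost without any 1 NaIO3-CaPB library or without NaIO3 library C (limma adjusted p up to 0.0847 and 0.0984). In the fit on the most abundant transcripts they were lost also (0.0523 and 0.0553), at unchanged log2FC, since each has 1 listed transcript, while those of NQO1, GCLM and FTL held in each of the 14 alternatives.

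Antioxidant enzymes outside that list did not pass as a group. Of 23 measured, 2 rose, 1 fell and 20 did not pass, with 2 risen and 2 fallen adjusted over the list alone (median log2FC 0.09, camera adjusted p = 0.607). Mitochondrial thioredoxin reductase TXNRD2 rose from 5.83 ± 1.02 to 11.3 ± 0.284 FPKM, and the peroxiredoxin PRDX5 rose 1.16-fold. The glutaredoxin GLRX had a log2FC of -0.81 (limma adjusted p = 0.05 as rounded, just below the threshold), a call lost on omission of any 1 library (up to 0.152). Manganese superoxide dismutase SOD2, at 18.2 ± 4.11 and 16.8 ± 2.27 FPKM with and without CaPB, and catalase CAT, at 51.6 ± 2.02 and 51.8 ± 8.87, did not differ by more than their spread (limma adjusted p = 0.749 and 0.979). In the list of iron handling and ferroptosis genes, 2 of 21 rose, 4 fell and 15 did not pass, with 5 each way adjusted over the list alone (camera adjusted p = 0.956). Its median log2FC was 0.00 and its mean -0.16, so the members that moved did not share a direction. HMOX1, FTL and SLC7A11, which are also NRF2 targets, fell, and the iron-regulatory aconitase ACO1 rose (log2FC 0.82). The TXNRD2 and ACO1 calls were lost without NaIO3-CaPB 1, 2 or 3 or NaIO3 library C (adjusted p up to 0.0642 and 0.0739), and that of PRDX5 on omission of any library but B (up to 0.145). On the most abundant transcripts GLRX (0.0898) and ACO1 (0.0666) did not pass.

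Heat shock and proteasome transcripts were lower. Of 20 heat shock genes, 9 fell, 0 rose and 11 did not pass, and 14 fell adjusted over the list alone (median log2FC -0.37, camera adjusted p = 2.72e-05, with an adjusted p = 0.352 with an estimated correlation). The co-chaperone STIP1 fell from 156 ± 2.9 to 109 ± 0.888 FPKM, and DNAJA1, HSP90AA1 and FKBP4 had log2FC of -0.68, -0.55 and -0.52. Of 31 proteasome subunits, 6 fell, 0 rose and 25 did not pass, with 11 fallen adjusted over the list alone. Their median log2FC was -0.30, and 30 of the 31 were lower (camera adjusted p = 1.29e-06, with an adjusted p = 0.282 with an estimated correlation). PSMD14 had a log2FC of -0.64, PSMC1 -0.49, PSMD1 -0.32 and PSMC4 -0.83. Without NaIO3 library B, 9 heat shock genes and 7 proteasome subunits fell. Chaperones of the endoplasmic reticulum included 2 falls and 0 rises among 20, with 18 not past the test and 2 fallen adjusted over the list alone (median log2FC -0.17, camera adjusted p = 0.0933). The falls were those of DNAJC3 (-0.35) and DNAJB9 (-0.71). Once NaIO3 library B was left out, 4 of these chaperones fell and the list passed (camera adjusted p = 0.00992), as it did with library weights (0.00678) and with the most abundant transcript (0.0364), but not with an estimated correlation and all 6 libraries (0.622). Omission of NaIO3-CaPB 3 ended the calls of DNAJA1, HSP90AA1, FKBP4, PSMD14, PSMC1, PSMD1, PSMC4, DNAJC3 and DNAJB9 (limma adjusted p from 0.0517 for DNAJA1 to 0.135 for PSMD1 and DNAJB9), and that of STIP1 held (0.048). The PSMC4 call was lost on omission of any 1 library, and those of PSMD1 and DNAJC3 without any library but NaIO3 library B. PSMC4 had a log2FC of -0.38 on its most abundant transcript and did not pass (limma adjusted p = 0.383). DNAJC3 (0.0603) and DNAJB9 (0.0766) did not pass in that fit either.

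Targets of ATF4, the effector of the integrated stress response, did not shift as a group: 1 of 27 rose, 1 fell and 25 did not pass, with 0 either way adjusted over the list alone (median log2FC 0.16, camera adjusted p = 0.246, and 0.872 with the estimated correlation of 0.678). The amino acid carrier SLC7A5 rose from 102 ± 22.1 to 166 ± 2.41 FPKM. ATF5 fell from 11.2 ± 0.823 to 7.41 ± 1.15 FPKM. The SLC7A5 call was lost without any 1 NaIO3-CaPB library or without NaIO3 library C (limma adjusted p up to 0.113). The ATF5 call was lost on omission of any 1 library (up to 0.143). Neither passed on the most abundant transcripts (0.0635 and 0.0531). The stress genes DDIT3 (log2FC 0.11, limma adjusted p = 0.834) and ATF3 (0.69, 0.223) did not pass. With 1 library left out the log2FC ran from -0.122 to 0.394 for DDIT3 and from 0.39 to 1.085 for ATF3. The NaIO3 libraries disagreed on this list. Relative to the NaIO3-CaPB mean its median was -0.65 in library A, -0.22 in library C and 0.34 in library B. Without library B, 4 members rose and 0 fell, and the list passed (median 0.39, camera adjusted p = 0.000306), and without library A its direction turned (-0.12, 0.611). The list therefore showed no consistent shift.

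Genes of mitosis were lower, and those of DNA replication were higher by less and not evenly across the NaIO3 libraries. All 30 measured genes of G2 and mitosis were lower in the NaIO3-CaPB libraries, and 20 of them fell past the test, with 28 adjusted over the list alone. The median log2FC was -0.76 (camera adjusted p = 1.5e-14, with an adjusted p = 0.379 with an estimated correlation). Cyclin B1, CCNB1, fell from 132 ± 10.8 to 69.8 ± 0.516 FPKM (log2FC -0.91, SE 0.08, limma adjusted p = 0.00411). The spindle checkpoint kinase TTK, the kinetochore motor CENPE and the anaphase activator CDC20 had log2FC of -0.96, -0.97 and -0.98. Of 34 genes of DNA replication, 5 rose, 0 fell and 29 did not pass, with 10 risen and 2 fallen adjusted over the list alone (median log2FC 0.35, camera adjusted p = 0.0064, with an adjusted p = 0.622 with an estimated correlation). Of the 34, 10 were lower. Relative to the NaIO3-CaPB mean the list's median was -0.09 in NaIO3 library A, -0.44 in B and -0.38 in C, so library A hardly showed the shift. With the most abundant transcripts the list's median log2FC was 0.22. The replicative helicase subunit MCM2 rose from 12.1 ± 1.25 to 23.8 ± 3.53 FPKM. CDC45 and the polymerase POLE each had a log2FC of 0.54, and UHRF1 0.40. Without NaIO3 library B, 21 mitotic genes fell and 2 replication genes rose. On omission of NaIO3-CaPB 1 the calls of MCM2, CDC45, POLE and UHRF1 were lost (limma adjusted p = 0.065 for MCM2, up to 0.135 for UHRF1). The UHRF1 call was lost on omission of any other library too, and that of POLE without any but NaIO3 library A. With the most abundant transcript alone the calls of TTK (0.505), CENPE (0.433), CDC45 (0.0652), POLE (0.0697) and UHRF1 (0.338) were lost. Of 31 replication-dependent histone genes on the list, 6 passed the filter. None of these 6 passed limma's test, where 0 rose and 0 fell in the list alone too (camera adjusted p = 0.709). The smallest p was that of H2BC5 (log2FC -0.31, limma adjusted p = 0.397), which passed with library weights (-0.63, 0.0408).

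Among 24 targets of p53, 1 rose, 4 fell and 19 did not pass, with 1 risen and 5 fallen adjusted over the list alone. The median log2FC was -0.15 (camera adjusted p = 0.139). Without NaIO3 library B, 2 rose and 3 fell. PMAIP1, a promoter of cell death, fell from 18.0 ± 1.49 to 8.55 ± 0.7 FPKM and GADD45A rose from 26.7 ± 1.79 to 43.8 ± 0.885. RRM2B had a log2FC of -0.58 and TIGAR -0.48. The cell cycle inhibitor CDKN1A, at -0.40, lay at the threshold (limma adjusted p = 0.0495), and its call was lost in 10 of 14 alternatives, among them quantile normalization (0.056). Of 26 apoptosis regulators and caspases, 1 rose, 1 fell and 24 did not pass, with the same counts adjusted over the list alone (median log2FC -0.12, camera adjusted p = 0.453). PMAIP1 was the fall and the survival factor BCL2L1 the rise (log2FC 0.40). Without NaIO3-CaPB 3, RRM2B, TIGAR and BCL2L1 no longer passed (limma adjusted p up to 0.129 for BCL2L1). The TIGAR call was lost on omission of any 1 library. Those of RRM2B and BCL2L1 were lost without any 1 NaIO3-CaPB library or without NaIO3 library C. On the most abundant transcripts BCL2L1 (0.525), CDKN1A (0.241), RRM2B (0.0529) and TIGAR (0.0641) did not pass.

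Enzymes of cholesterol synthesis, induced by the sterol-regulated transcription factor SREBP2, rose as a group. Of 23 measured, 17 rose, 0 fell and 6 did not pass, and 21 rose adjusted over the list alone. The median log2FC was 1.09, and 22 of 23 were higher (camera adjusted p = 6.75e-13, with an adjusted p = 0.379 with an estimated correlation). HMGCS1, the synthase at the head of the pathway, averaged 16.7 ± 13.2 FPKM with NaIO3 and 96.7 ± 2.12 with CaPB added, 5.78-fold higher, or 10.5-fold without NaIO3 library A. DHCR7, which makes cholesterol in the last step, rose from 21.6 ± 2.39 to 66.3 ± 4.21 FPKM (log2FC 1.58, SE 0.10, limma adjusted p = 0.00213). FDPS had a log2FC of 1.45, INSIG1, a sterol-regulated brake on the pathway, 1.47 and TM7SF2 1.09. Without NaIO3 library B 18 members rose. INSIG1 did not pass with its most abundant transcript alone (limma adjusted p = 0.0569).

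Genes of hypoxia and glycolysis were lower: 14 of 31 fell, 0 rose and 17 did not pass, and 18 fell and 1 rose adjusted over the list alone (median log2FC -0.70, camera adjusted p = 8.25e-08, with an adjusted p = 0.379 with an estimated correlation). Hexokinase HK2 fell from 22.6 ± 5.91 to 7.32 ± 0.361 FPKM, lactate dehydrogenase LDHA from 461 ± 47.1 to 254 ± 32, and triose phosphate isomerase TPI1 from 616 ± 70.7 to 378 ± 9.53. The histone demethylase KDM3A, induced by hypoxia, had a log2FC of -0.91. Without NaIO3 library B, 10 fell and 1 rose. Each of these 4 named calls was lost on omission of at least 1 NaIO3-CaPB library (limma adjusted p up to 0.0525 for LDHA and 0.0571 for KDM3A), and KDM3A did not pass with its most abundant transcript (0.49).

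Few respiratory chain transcripts passed the test. Among 13 mitochondrially encoded mRNAs, MT-ND2 fell (log2FC -0.25), MT-ND3 rose (0.20) and 11 did not pass, with 1 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.788). The median log2FC was 0.03 and the mean -0.02, opposite in sign. Of 41 nuclear-encoded subunits, 1 rose, 0 fell and 40 did not pass, with 0 either way adjusted over the list alone (median log2FC 0.03, camera adjusted p = 0.408). The 1 was ATP5PO (log2FC 0.49). The calls of MT-ND3 and ATP5PO were lost on omission of any 1 library (limma adjusted p up to 0.132 and 0.129). That of MT-ND2 was lost without any 1 NaIO3-CaPB library or without NaIO3 library C (up to 0.0967). Without the intensity trend all 3 were lost too (up to 0.144), and with quantile normalization MT-ND2 had a log2FC of -0.11 (0.204). MT-ND3 (0.0562) and ATP5PO (0.0666) did not pass on the most abundant transcripts.

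Genes of the extracellular matrix and of mesenchymal cells rose. Of 28 measured, 13 rose, 0 fell and 15 did not pass, and 18 rose and 1 fell adjusted over the list alone (median log2FC 0.55, camera adjusted p = 1.8e-08, with an adjusted p = 0.282 with an estimated correlation). TAGLN, a smooth muscle actin-binding protein, rose from 6.08 ± 0.564 to 37.8 ± 1.73 FPKM, 6.21-fold higher (log2FC 2.46, SE 0.09, limma adjusted p = 0.000761). CCN1 rose from 80.0 ± 20.6 to 346 ± 4.7 FPKM, and the basement membrane collagen COL4A1 from 44.8 ± 1.46 to 78.4 ± 1.55. These 3 calls held in all 14 alternatives. Without NaIO3 library B, 14 members rose and 1 fell.

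Of 33 markers of RPE and pigment cells on the list, 11 passed the filter, so the result covers only those. They did not shift as a group: 1 of 11 rose, 2 fell and 8 did not pass. Adjusted over the list alone, 2 rose and 3 fell (median log2FC -0.03, camera adjusted p = 0.962). The keratin KRT8 rose from 196 ± 27.4 to 318 ± 6.84 FPKM, the transcription factor OTX2 fell from 31.7 ± 4.33 to 20.9 ± 0.235, and the retinaldehyde-binding protein RLBP1 fell from 4.79 ± 0.609 to 2.9 ± 0.325. RPE65, the visual cycle isomerase, was not analysed here. None of 15 junction genes passed limma's test, nor did any adjusted over the list alone (0 risen and 0 fallen, median log2FC -0.01, mean 0.05, camera adjusted p = 0.711). The smallest p was that of the polarity gene PARD6B (log2FC 0.38, limma adjusted p = 0.0587), which passed with library weights (0.0142) and without the intensity trend (0.0448). The calls of KRT8, OTX2 and RLBP1 were lost without NaIO3-CaPB 1, 2 or 3 or without NaIO3 library C (limma adjusted p up to 0.071, 0.0984 and 0.126), and that of RLBP1 without NaIO3 library B as well. OTX2 (0.051) and RLBP1 (0.0757) did not pass on the most abundant transcripts.

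Interferon-stimulated genes were lower than in 2 of the 3 NaIO3 libraries. Of 19 measured, 7 fell, 1 rose and 11 did not pass, with 9 fallen and 1 risen adjusted over the list alone (median log2FC -0.35, camera adjusted p = 0.0277, with an adjusted p = 0.568 with an estimated correlation). Relative to the NaIO3-CaPB mean the list's median was 0.44 in NaIO3 library A, 0.38 in C and 0.08 in B, and leaving out library A moved the median log2FC to -0.19. IFI44 fell from 4.74 ± 0.322 to 0.926 ± 0.312 FPKM, the antiviral IFIT1 from 19.3 ± 5.07 to 8.25 ± 0.964, IFI6 from 47.7 ± 1.56 to 27.4 ± 6.5 and BST2 from 1.76 ± 0.601 to 0.272 ± 0.258. Without NaIO3 library B, 5 fell and 1 rose. The list did not pass without NaIO3 library A (camera adjusted p = 0.169), without NaIO3 library C (0.334) or among genes of at least 5 FPKM (0.242), and without NaIO3-CaPB 3 the calls of IFIT1, IFI6 and BST2 were lost while IFI44 held (limma adjusted p = 0.0319). Without NaIO3-CaPB 2 the NaIO3-CaPB mean of BST2 was 0.151 FPKM. IFIT1 (0.051) and BST2 (0.0615) did not pass on the most abundant transcripts.

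Inflammatory genes driven by NF-kB went both ways, with 2 of 16 risen, 2 fallen and 12 not past the test, and 3 each way adjusted over the list alone (median log2FC 0.12, mean -0.003, camera adjusted p = 0.597). The chemokine CCL5 fell from 2.51 ± 0.234 to 0.38 ± 0.203 FPKM and IL1B from 2.35 ± 0.272 to 1.13 ± 0.251, and the cytokines LIF and IL32 rose (log2FC 0.64 and 1.00). CXCL8 averaged 37.9 ± 2.39 FPKM with CaPB and 83.7 ± 40.1 without it (log2FC -0.99, limma adjusted p = 0.138) and did not pass, except without NaIO3 library A (-1.44, 0.00912) and with library weights (-1.16, 0.0117). IL6 lay below the filter, at no more than 0.675 FPKM in any library. Of 18 complement and inflammasome genes, 2 rose, 0 fell and 16 did not pass, with the same counts adjusted over the list alone and without NaIO3 library B (median log2FC 0.32, camera adjusted p = 0.0441, with an adjusted p = 0.568 with an estimated correlation). The central component C3 rose from 3.33 ± 0.975 to 12.1 ± 0.371 FPKM and CD55, which limits complement on the cell's own surface, from 27.6 ± 2.24 to 54.2 ± 3.43. The complement list did not pass in 9 of 13 alternatives (camera adjusted p up to 0.181), and without NaIO3-CaPB 1 the calls of LIF (0.0601), IL32 (0.0601) and IL1B (0.112) were lost. CD55 did not pass on its most abundant transcript (log2FC 1.13, limma adjusted p = 0.0715), nor did IL1B in that fit (0.065). IL32 was not among the genes tested in that fit.

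Of 21 immediate early genes, 2 rose, 3 fell and 16 did not pass, with 3 risen and 8 fallen adjusted over the list alone (median log2FC -0.28, camera adjusted p = 0.137). The list passed without NaIO3 library A (camera adjusted p = 0.0235), but not with an estimated correlation and all 6 libraries (0.705). The phosphatase DUSP1 rose from 42.5 ± 4.18 to 87.6 ± 2.68 FPKM and JUND from 55.4 ± 1.66 to 81.1 ± 3.34, and SPRY2 and DUSP4, both brakes on ERK signalling, had log2FC of -1.09 and -0.75. In the lysosome and autophagy list 1 of 36 rose, 3 fell and 32 did not pass, with 4 each way adjusted over the list alone (median log2FC 0.13, mean -0.01, camera adjusted p = 0.518). Galactosidase GLA fell from 20.9 ± 1.56 to 8.82 ± 0.686 FPKM, the protease CTSL had a log2FC of -0.85, ATG12 -0.68 and the hexosaminidase HEXA 0.48. Calcium handling genes included 3 falls and 0 rises among 23, with 20 not past the test and 5 fallen and 1 risen adjusted over the list alone (median log2FC -0.06, camera adjusted p = 0.518). These were S100A11 (-0.30), the calcium channel ITPR1 (-0.81) and the kinase CAMK2D (-0.47). Among 7 metallothionein and metal response genes the zinc exporter SLC30A1 fell (-0.83), MT1E rose (0.72) and 5 did not pass, with the same counts adjusted over the list alone (median log2FC -0.15, camera adjusted p = 0.483). None of 64 cytosolic ribosomal protein genes passed limma's test, nor did any adjusted over the list alone (0 risen and 0 fallen, median log2FC 0.06, camera adjusted p = 0.122). The list passed with library weights (camera adjusted p = 0.0165) and with the most abundant transcript (0.0336), but not with an estimated correlation (0.712). The smallest p was that of RPL13 (log2FC 0.27, limma adjusted p = 0.0536), which passed with median-ratio scaling (0.0448), with library weights (0.0122) and among genes of at least 5 FPKM (0.0484). Without NaIO3-CaPB 3, DUSP1, SPRY2 and GLA kept their calls (limma adjusted p = 0.0312, 0.0468 and 0.0312), while those of JUND, DUSP4, CTSL, ATG12, HEXA, S100A11, ITPR1, CAMK2D, SLC30A1 and MT1E were lost (up to 0.136 for CAMK2D). CAMK2D did not pass on its most abundant transcript (log2FC -0.90, limma adjusted p = 0.139), nor did CTSL (0.0727), ATG12 (0.0663) or MT1E (0.051). ITPR1 was not among the genes tested in that fit.

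Markers of other retinal cell types were scarce, so no list of them could be tested. Past the filter were 2 of 18 photoreceptor genes, 1 of 20 blood and immune genes, 1 of 14 endothelial genes and 3 of 17 genes of Mueller glia and neurons. CD68, a lysosomal protein of macrophages, fell from 23.4 ± 0.597 to 17.02 ± 1.84 FPKM (log2FC -0.44, limma adjusted p = 0.0397), a call lost on omission of any 1 library (up to 0.125) and on its most abundant transcript (0.141). PDE6B (0.20, limma adjusted p = 0.751), ROBO4 (0.21, 0.494) and SNAP25 (1.04, 0.411) did not pass. ROBO4 had the opposite sign on its most abundant transcript (-0.18, 0.671). With 1 library left out the log2FC of PDE6B ran from -0.071 to 0.586. SNAP25 was at 7.132 FPKM in NaIO3-CaPB 1 and at no more than 0.094 in any other library. That library alone carried SNAP25 past the filter.

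**Figure D2:**
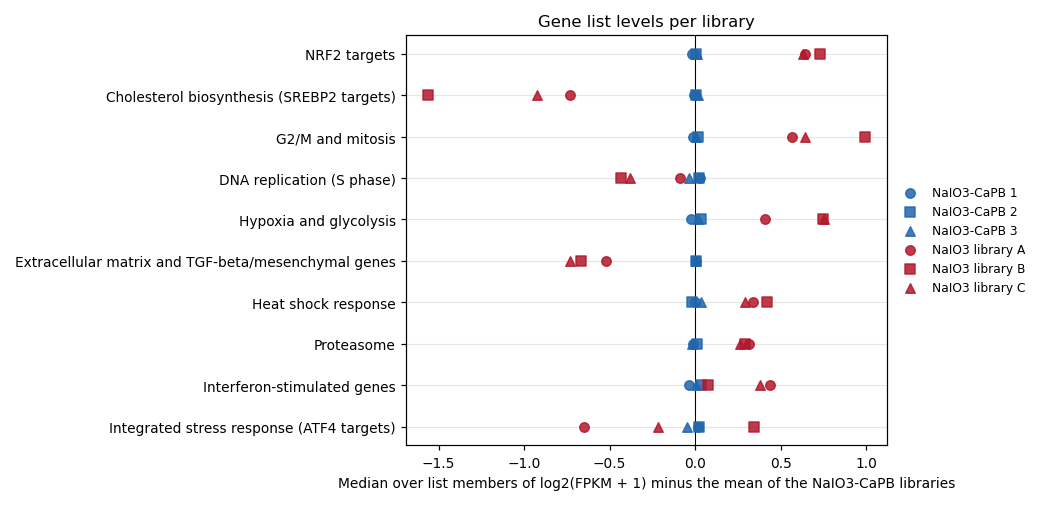
Level of 10 lists in each library, as the median over list members of log2(FPKM + 1) minus the mean of the NaIO3-CaPB libraries (horizontal axis, log2 units), 1 symbol per library. NaIO3 libraries lay at 0.63 to 0.73 for NRF2 targets and at -1.56 to -0.73 for cholesterol synthesis, and they spread from -0.65 to 0.34 for ATF4 targets.

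Single transcripts were also tested. Limma called 227 of 21736, with 132 higher and 95 lower, and 162 of them changed by at least 2-fold. They belonged to 203 genes, 156 of which were also called at the gene level. The median residual SD was 0.33 log2 units for transcripts and 0.17 for genes. In 8 genes, transcripts were called in both directions: CTSA, HLTF, INTS6, SPRYD7, STRBP, TNPO3, UBE2E3 and ZNF146, all named after their values were seen. ZNF146-201 averaged 27.5 ± 1.2 FPKM with CaPB and 1.83 ± 0.604 without it (log2FC 3.35, limma adjusted p = 0.00816), and ZNF146-202 averaged 1.83 ± 0.305 and 25.5 ± 4.88 (-3.22, 0.00822), while the gene's sum did not pass (0.11, 0.604). CTSA, the lysosomal cathepsin A, showed the same kind of shift, with CTSA-201 at 22.0 ± 3.32 against 2.57 ± 0.99 FPKM and CTSA-203 at 16.7 ± 2.12 against 54.7 ± 14. Omitting 1 library left between 39 transcript calls (without NaIO3-CaPB 1) and 197 (without NaIO3 library A).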

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

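The most abundant transcript per gene and the transcript alternatives, except the pseudocount, were chosen only after the data were seen. No paired analysis was possible because the NaIO3 columns carry no replicate number, so the replicate block was not run; DESeq2 and count filters were not run for want of counts. Directions of all 10 called lists were kept in 13 alternatives, and 8 of them stayed past the threshold in 13 of 13; the intensity trend, which camera does not use, is not among these. With an estimated correlation, 0 of the 10 lists passed: the camera adjusted p was 0.282 for NRF2 targets, extracellular matrix and proteasome, 0.352 for heat shock, 0.379 for mitosis, cholesterol synthesis and hypoxia, 0.568 for interferon and complement and 0.622 for DNA replication. That setting uses the correlation measured between a list's genes, 0.60 for mitosis and 0.56 for cholesterol synthesis but 0.037 for proteasome. It also takes its degrees of freedom from the libraries, where the preset correlation takes them from the genes. What each difference contributed was not tested, so the lost calls do not by themselves show correlation within the lists. Fry called 9 of the 10, with DNA replication at an adjusted p of 0.0699, and also metallothioneins (0.0108) and apoptosis regulators (0.0485), which camera did not call. The complement list did not pass with a pseudocount of 0.1 (0.0504), no filter (0.0953), median-ratio scaling (0.0559), library weights (0.158) or the most abundant transcript (0.181), and ranged from 0.018 to 0.118 with 1 library left out. The interferon list did not pass at a mean of 5 FPKM (0.242) and ranged from 0.0093 to 0.334 with 1 library left out; the causes were not tested. Gene calls rose to 3578 with library weights (1646 higher, 1932 lower, 351 of at least 2-fold), including 1183 of the 1185, and numbered 469 with the most abundant transcript (235 higher, 234 lower); the cause was not tested. With 1 library left out, gene calls ranged from 169 to 1381 (higher 96 to 684, lower 73 to 697, at least 2-fold 104 to 335) and transcript calls from 39 to 197. Fewer libraries leave less power, yet omitting NaIO3 library A raised gene calls; omitting NaIO3-CaPB 1, 2 or 3 left 215, 245 and 169, and omitting NaIO3 library C 330. Transcript calls were 362 at a mean of 5 FPKM, 442 with library weights and 132 without the intensity trend. Of 94 called named genes, 94 kept their direction and 30 passed in every alternative that tested them. Of the 94, 56 lost the call with some library left out and 42 under some other alternative. Of the 12 not called, 5 passed somewhere. With the most abundant transcript 38 lost the call, among them 12 with 1 listed transcript and an unchanged fold, where the other genes in the fit moved the adjusted p. These counts for named genes cover 14 alternatives, but a gene that an alternative's filter left out could not lose its call there. The filter at a mean of 5 FPKM left out C4BPB, CCL5 and IFI44, among others. IL32 and ITPR1 were not tested on their most abundant transcripts. Depth is unknown, so it is open which low genes were limited by it.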

Other observations

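The tests of the graded response, of matched random lists and of YAP targets, and the ERK list, were chosen or reworded only after results were seen, and the bound of the test on transcripts called in opposite directions was made stricter after its result was seen. A list of 20 feedback regulators and targets of ERK signalling was written after some of its members had been seen. Of its 18 measured members, 8 fell and 1 rose, with a median log2FC of -0.76. The unadjusted camera p was 0.00023, or 0.156 with an estimated correlation. The transcription factors ETV1 and ETV4 fell from 18.5 ± 3.33 to 5.42 ± 2.02 FPKM and from 4.66 ± 1.75 to 1.22 ± 0.0892 (SD, n = 3), and the phosphatase DUSP6 from 8.66 ± 4.31 to 2.17 ± 0.372. Over the 10 measured members not noted as seen, 2 fell and 1 rose, with a median of -0.24. Camera gave them an unadjusted p of 0.369, so no shift of the group was shown beyond the genes that prompted the list.

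The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1185 gene calls against at most 2 in any other, 224 against 2 for calls of at least 2-fold, and 227 against 22 for transcript calls; in each case 1 split, the real one, gave as many. For gene lists the real split gave 10 calls and so did another one, of NaIO3-CaPB 1, NaIO3-CaPB 2 and NaIO3 library A against the rest, so 2 of the 10 splits gave as many. The number of lists past camera with a preset correlation was therefore no higher in the real split than in that one. Each split other than the real one puts 2 libraries of a group with 1 of the other group. Part of the real difference then stays between its sides and part enters the spread within them. The first can add list calls and the second can remove gene calls. These counts therefore cannot decide how many calls would arise without a group difference.

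The lower NRF2 targets were weighed against 3 technical explanations. Library scaling is argued against by the list's median log2FC, which was -0.625 under the weaker of median-ratio scaling and quantile normalization. A single NaIO3 library is argued against by a median of -0.607 in the weakest omission of one of them. Of 10000 random lists matched on transcript length and mean expression, none had a median as low (permutation p = 0.0001, the smallest they can give), which argues against a bias of transcript length. Oxidant load that differed between groups and a direct effect of CaPB on NRF2 remain open, since libraries without NaIO3 and with CaPB alone were not analysed here. A difference between culture batches remains open too, since the culture batch of each library is not given in the sources used here.

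The NaIO3 libraries were spread along the axis that separates the groups, and the median SD of genes was 0.18 log2 units among them against 0.11 among NaIO3-CaPB libraries. One candidate explanation is a graded extent of 1 response. It would make the difference between a pair of NaIO3 libraries resemble the distance of the remaining one from the NaIO3-CaPB mean, and Spearman's rho across genes, which are not independent, was 0.248, 0.232 and 0.0512 in the 3 arrangements, too mixed to decide. A difference tied to transcript length is argued against for libraries A and B, since length correlated with library B minus library A at a rho of 0.0708. FPKM are already divided by length, and RNA integrity and coverage along transcripts were not analysed here, so degradation remains open. The ATF4 targets lay in the order of the axis among the NaIO3 libraries (A, C, B), but the NaIO3-CaPB libraries, at the far end of the axis, had a level between those of C and B.

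In 8 genes transcripts were called in opposite directions, which could come from isoform use or from an arbitrary assignment of reads between overlapping isoforms. Other splits gave at most 2 such genes, but they also called fewer transcripts: 2 of 20 genes with a called transcript (10.0%) in that split against 8 of 203 (3.94%) in the real one. Arbitrary assignment and isoform use cannot be told apart here, because the table holds no reads across exon junctions.

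A hypothesis is that targets of YAP, a transcriptional coactivator that responds to cell tension and attachment, were higher with CaPB as a group. It arose from the higher ANKRD1, CCN1, CCN2 and TGFB2. A YAP target list was written after the gene results had been looked at, and members noted as seen by then were left out. Of its 16 other measured members, 8 rose and 1 fell, with a median log2FC of 0.445. The unadjusted camera p was 7.05e-06, or 0.0363 with an estimated correlation. The lists fixed beforehand have p-values adjusted over all tested lists, so 0.0363 cannot be set beside their values with an estimated correlation. It does not show that the YAP list held up where those lists did not. Among the 16 members, named after their values were seen, the coagulation initiator F3 rose from 106 ± 1.77 to 230 ± 12.6 FPKM. CRIM1 rose from 60.5 ± 7.35 to 154 ± 3.1, and the ectonucleotidase NT5E fell from 145 ± 5.5 to 73.1 ± 1.33. F3, CRIM1 and NT5E had limma adjusted p of 0.0018, 0.003 and 0.0021, below the 0.0041 of CCN1, which was noted as seen. They may have been seen too, so the 16 members are not an independent check. The test was run on the same libraries that prompted it, and it may equally reflect other regulators of matrix and contractile genes, so it is consistent with the hypothesis and no more.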
